A study of Rattus norvegicus with 3 samples.

How the data were processed

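Soleus RNA of rats was measured on Affymetrix Rat Gene 1.0 ST arrays, which carry several short probes for each probe set. RNA of the 6 rats of a group was pooled, and 1 array was used for each of the 3 groups, irradiation alone (Ct), denervation with irradiation (DN) and tail suspension with irradiation (TS). The series text speaks of 2 arrays, whereas 3 samples with values were used here. Each sample was placed in its group by its label.

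Per the labels and the submitters' processing notes, the deposited values were made with Affymetrix Expression Console by RMA (background correction, normalization across arrays and summary of the probes of a set by median polish) in a core-exon analysis, and they were read as log2 values. The labels do not state the base of the logarithm; the values run from 1.77 to 13.99 with array medians near 6.3, and folds given here rest on base 2. The tool's version, the annotation and the genome build are not given in the sources used here, so no coordinates are given. Median polish of 3 arrays can return exactly the same value for 2 of them, and 42.9% of tested genes were equal on Ct and DN, 24.7% on Ct and TS and 26.3% on DN and TS. A difference of 0 therefore does not show that a gene did not differ. The number of arrays limits the precision.

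Gene names came from the platform annotation, in which 15310 of 29170 probe sets had 1 gene symbol, 323 had several and 13537 had none. The gene identifiers of 15279 probe sets were found in a table of the GRCr8 assembly, used only for names, and no symbol changed. Probe sets with several symbols or none were left out of the comparisons. A gene with several probe sets was represented by the brightest, and of 14506 genes the 10154 whose mean over the 3 arrays was at or above the 30th percentile (5.72) were compared. Over 401 genes with a further probe set past this limit, the median disagreement between both was 0.03 (log2) for DN minus Ct and 0.11 for TS minus Ct, and the 95th percentile 0.33 and 0.73.

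Differences of log2 values were taken for DN minus Ct, TS minus Ct and DN minus TS. With 1 array per group there is no spread between samples, so no p-value was computed; genes were counted at a 2-fold limit and members of gene lists at a 1.5-fold limit. The median of each list was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A list was said to lie above or below its range when its median was past the 97.5th or the 2.5th percentile, as a description of these arrays. The 38 lists, the named genes' rule, the filter and the limits were set before the data were examined; 3 lists had fewer than 5 measured members and have no percentile. Some genes sit on more than 1 list, so lists are not independent.

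The rule for named genes took the 10 highest and 10 lowest differences per comparison with Ct, the 6 highest and 6 lowest of DN against TS, up to 4 members of each list with the largest differences, and Myog, Chrna1, Chrng, Myh7, Myh4, Fbxo32, Trim63 and Cdkn1a in every case. Symbols of uncharacterised loci, olfactory and vomeronasal receptors and small RNAs were passed over. Chrnb1, Chrnd, Mylk2, Myoz1, Ache, Colq, Plin2, Hpx, Hpd, Fkbp5, Klf15, Zbtb16 and the genes named in the closing observations were named after their values were seen. Probe sets of closely related genes, such as the myosins Myh1 and Myh4, the metallothioneins Mt1 and Mt2A and ribosomal proteins, may share signal.

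Because both comparisons with Ct use the same array, 3 unchanged arrays were simulated, with noise taken from the DN minus TS differences by expression level, and their overlap and correlation were set beside those observed. The procedure was tested on simulated data for DN minus Ct over 10154 genes. At changes of 1.5, 2.0, -1.5 and -2.0 (log2) it called 88.0%, 100.0%, 96.0% and 96.0% of 50 genes each, and it called 143 of 9954 unchanged genes (1.44%). Of 100 unchanged lists, 5 stood apart, and all 20 lists shifted by 0.5 were recovered. The noise was again scaled to the DN minus TS differences and drawn independently for each gene without tied values. These shares therefore check the procedure and are not rates of false calls for these arrays, whose spread between samples is not known. Shifts smaller than 0.5 were not simulated.

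Alternatives were centring each array on its median, removing a loess trend on mean expression (span 0.3), quantile normalization, 32 added on the linear scale, no filter or a filter at the 50th percentile, the mean of a gene's probe sets or only genes with 1 probe set, limits of 1.5-fold and 3-fold, list means, and random lists not matched on expression. Leaving out genes with equal values was added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.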

Results

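Gene expression was profiled in the soleus, a slow-twitch postural muscle of the hind limb, of rats aged 7 weeks from a strain labelled Brown. All 3 groups were irradiated over 2 weeks to a total of 50 mSv. Group Ct received irradiation alone, in group DN the muscle was also denervated, and group TS was also suspended by the tail, a model in which the hind limbs carry no load. The series is titled as a study of simulated spaceflight, and the comparisons of DN and TS with Ct ask how the muscle differs when it loses its nerve or its load under the same irradiation. RNA from 6 rats per group was pooled and measured on 1 array per group, so there were no replicates, no test between groups could be made, and each difference describes these pools. An unirradiated group is not among the samples, so the effect of irradiation itself was not measured. The array medians over 29170 probe sets were 6.32 in Ct, 6.33 in DN and 6.35 in TS (log2), and 10154 named genes were bright enough to compare. Over those genes the median of the TS array lay 0.13 above that of Ct and the median of DN 0.01 above it, whereas the median of the differences gene by gene was 0.02 for TS minus Ct and 0.00 for DN minus Ct.

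In denervated soleus, genes of the acetylcholine receptor and of immature muscle stood far above Ct. Chrng, the receptor subunit of fetal muscle, was higher by 4.76 (log2), or 27.1-fold, and Chrna1, the alpha subunit, was higher by 3.58. Musk, a receptor tyrosine kinase needed to cluster these receptors, was higher by 2.57, and its partner Lrp4 by 1.81. Of 16 neuromuscular junction genes measured, 7 were at least 1.5-fold higher and 2 were lower, the latter being acetylcholinesterase (Ache, -1.14) and its collagen tail (Colq, -1.03). The median of this list was 0.33, above its random lists, whose middle 95% ran from -0.01 to 0.06.

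Regulators known to respond to denervation were higher in DN as a group. Of 12 measured, 9 were at least 1.5-fold higher and none was lower, with a median of 2.05 against a random range of -0.05 to 0.13. The transcription factor Runx1 was higher by 3.67, the myogenic factors Myod1 and Myog by 3.44 and 1.86, and the stress-response gene Gadd45a by 3.15. Cdkn1a, which encodes the cell cycle inhibitor p21, was higher by 3.95. Developmental muscle genes had a median of 1.86 and 9 of 13 members at least 1.5-fold higher, among them the stretch-responsive Ankrd1 (4.23), cardiac and embryonic troponin Tnnt2 (3.31) and embryonic myosin Myh3 (2.25). Myf5, a factor of muscle precursor cells, was higher by 2.00, and 4 of 12 satellite cell markers were at least 1.5-fold higher and none lower, with a median of 0.00 and a mean of 0.26, both within their random range.

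Among contractile genes, fast forms were higher and slow forms lower in DN. Of 16 fast-fibre genes, 9 were at least 1.5-fold higher, and the list median was 1.20 against a random range of -0.08 to 0.12. The largest differences were in the calcium buffer Pvalb (4.34, 20.2-fold) and the fast myosins Myh1 (3.73) and Myh4 (2.02). Exceptions were the fast-muscle kinase Mylk2 (-1.67) and the Z-disc gene Myoz1 (-1.0), the 2 members that were at least 1.5-fold lower. Of 15 slow-fibre genes, 8 were at least 1.5-fold lower and 1 was higher, with a median of -0.59. Ankrd2 stood at -2.0, the slow myosin Myh7b at -1.32 and the light chain Myl3 at -1.30, while Myh7, the main slow myosin, stood at -0.56 and the calcium pump regulator Sln was higher by 1.19. Myh7 read 13.62 in Ct, near the highest value of that array (13.99), where differences can be compressed, as can those of Myl3 and Ankrd2.

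Genes of mitochondrial energy metabolism were lower in DN as a group. Of 45 oxidative phosphorylation subunits, 38 were at least 1.5-fold lower and none was higher, with a median of -0.85 and a random range of 0.00 to 0.07. Ndufs3 of complex I stood at -1.62, the ATP synthase subunit Atp5mc1 at -1.53 and Cox8b of complex IV at -1.48. Tricarboxylic acid cycle genes had a median of -0.68, with 11 of 18 at least 1.5-fold lower, including the mitochondrial pyruvate carrier genes Mpc1 (-1.90) and Mpc2 (-1.40). Fatty acid uptake and oxidation genes had a median of -0.81 and 19 of 27 at least 1.5-fold lower, such as Hadh (-2.0) and Fabp3 (-1.62). The 3 higher members of that list were Angptl4 (2.29), Ucp3 (1.89) and Plin2 (1.55). Oxidative regulators and angiogenic genes had a median of -0.76, with 12 of 19 at least 1.5-fold lower, led by Perm1 (-4.32), Fndc5 (-1.41) and Ppara (-1.27). Glycolysis and glycogen genes differed less, with a median of -0.20 and 6 of 24 at least 1.5-fold lower, among them the glucose transporter Slc2a4 (-1.92), Ldhb (-1.5) and Gys1 (-0.98).

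Lists of protein breakdown genes had small medians in DN, although single ubiquitin ligases differed by more than 2-fold in both directions. The ubiquitin ligase Fbxo32 was higher by 0.13 and Trim63 by 0.31, both short of 1.5-fold, while Fbxo31 (1.12) and Fbxo30 (1.09) were higher and Asb2 (-2.17) lower. The list of 16 ligase and ubiquitin genes had a median of 0.03, within its random range. Proteasome subunits had a median of 0.11, just above a random range that ended at 0.09, with none of 31 members at least 1.5-fold different; taken as a mean (0.14), or without genes of equal value (0.12), this list lay within its range. Autophagy and lysosome genes had a median of 0.09 against an upper bound of 0.08, with Wipi1 lower (-0.88) and Ctsl higher (0.67), and this call also ended under 3 alternatives.

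Other lists in DN were mixed. The p53 target list had a median of 0.15, above a range of 0.00 to 0.06, with 5 of 17 members at least 1.5-fold higher and 1 lower. Its members Cdkn1a and Gadd45a also sit among the denervation-responsive regulators, Phlda3 stood at 1.20 and Tp53inp1 at 0.91. Growth factor and FOXO signalling genes had a median of 0.02, within range, although Fst, an antagonist of myostatin, was higher by 2.72, the metallothioneins Mt1 and Mt2A, which are close copies, by 2.65 and 2.28, and Igfbp5 by 1.23; the mean of the list (0.39) lay above its range. Excitation-contraction coupling genes had a median of 0.00 and a mean of -0.25 that lay below its range, with Cav3 (-1.72), Clcn1 (-1.72) and Kcnj2 (-1.49) lower and Cacnb1 (1.14) higher. Medians within their ranges were found for heat shock genes (-0.06), antioxidant genes (0.00), ribosomal protein genes (0.05), extracellular matrix genes (0.03), polyamine genes (-0.03, with a mean of 0.08) and interferon and antigen presentation genes (0.00). Cell cycle genes had a median of -0.04, below a random range that tied values narrowed to 0.00 at both ends, with 2 of 17 at least 1.5-fold lower. Single members of the other lists differed more, including Hspb6 (-1.47), Hspb3 (-1.10), Hspb8 (1.02), Gpx1 (-1.22), Lox (1.47), Timp1 (1.09), Rpl3 (1.06), Sms (0.84) and Cd74 (0.76).

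Markers of other cell types also differed between the DN and Ct pools. Adipocyte markers had a median of 0.48, above a range of -0.02 to 0.08, with Scd (2.22), Adipoq (2.10) and Cidec (1.32) higher. Endothelial markers had a median of -0.27 and smooth muscle and pericyte markers of -0.21, both below their ranges, with Kdr (-0.87), Flt1 (-0.69), Kcnj8 (-0.87) and Cspg4 (-0.83) lower. Tendon markers had a median of -0.80, with 5 of 9 at least 1.5-fold lower, among them Chad (-1.62), Tnmd (-1.61) and Kera (-1.19), and 3 higher. Macrophage markers had a median of 0.18, above a range that ended at 0.10, with none of 13 past 1.5-fold, and the complement and cytokine list had a median of 0.08, with Cfd (1.32), C1s (0.85) and Ccl7 (0.83) higher. Neutrophil and mast cell markers had a median of -0.10, below their range, with none of 6 past 1.5-fold. The calls for these last 3 lists ended under at least 1 alternative. Fibroblast (0.00), lymphocyte (0.02) and Schwann cell and nerve markers (0.00) lay within their ranges, with Cnp (0.79) the largest difference among the latter.

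In all, 227 genes were at least 2-fold higher and 227 at least 2-fold lower in DN than in Ct. Outside the lists, the highest differences included Emb (4.35), Ctxn3 (4.21), Ppp1r14c (3.82), the kallikrein Klk1 (3.82) and Tph1 (3.75), an enzyme of serotonin synthesis. The lowest were the methyltransferase gene Mettl21c (-5.00), Lgi1 (-4.50), the carbonic anhydrase Car14 (-4.17), the sodium channel subunit Scn4b (-3.99), Asb18 (-3.59), the interferon-inducible Ifit1 (-3.57), Itgb1bp2 (-3.29), Lynx1 (-3.18) and Zfp474 (-3.17). Ifit1 (3.71), Lgi1 (5.02) and Car14 (5.03) in DN and Ppp1r14c in Ct (5.55) read below the filter limit of 5.72, so the size of their differences is less certain. Of 9 genes past 2-fold that had a further probe set past the filter limit, 8 differed in the same direction there and 5 were again past 2-fold.

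**Figure D1:**
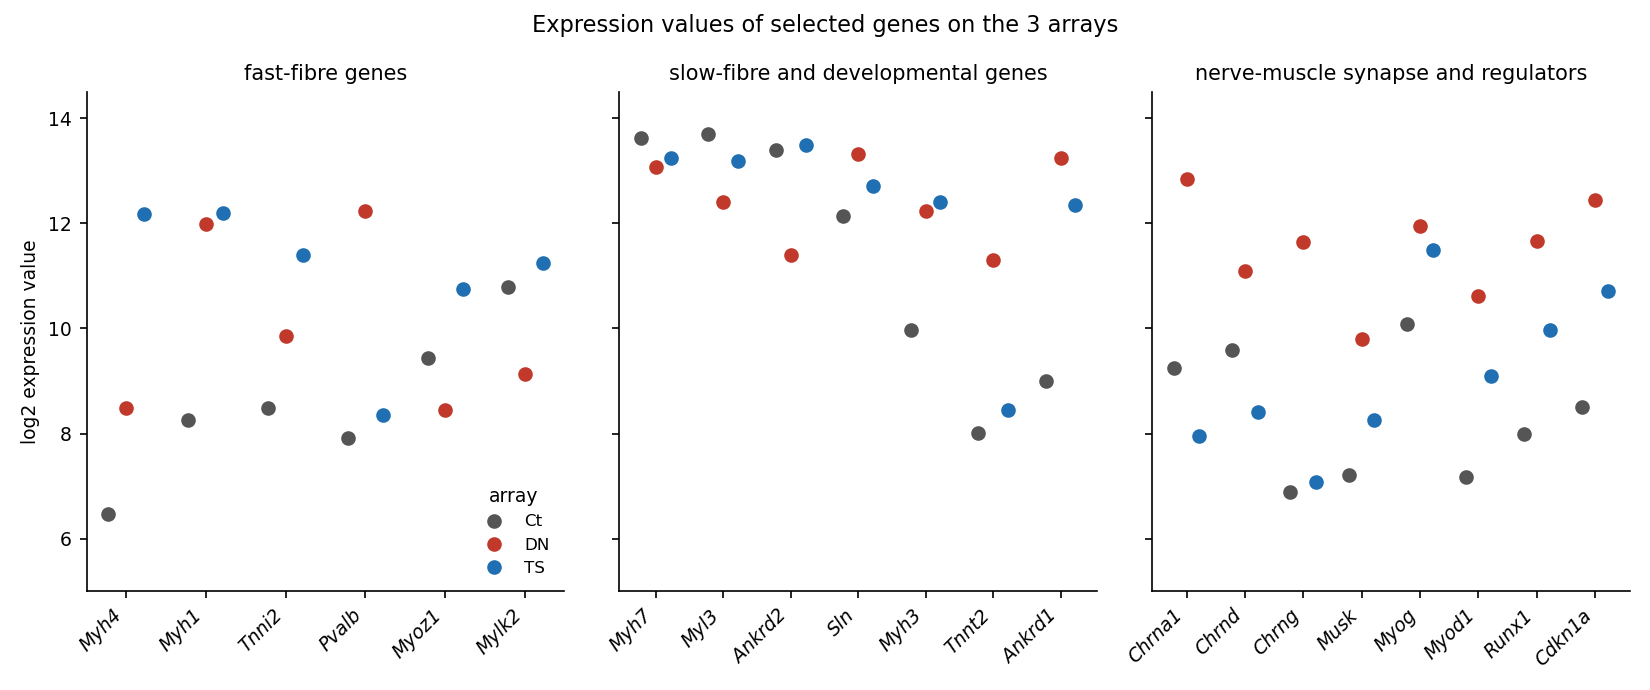
Expression values (log2, vertical axis) of selected genes on the Ct, DN and TS arrays, each point being 1 array of RNA pooled from 6 rats. Myh4 stood at 6.46 in Ct, 8.48 in DN and 12.19 in TS, whereas Pvalb stood at 7.91, 12.24 and 8.35 and Chrna1 at 9.25, 12.84 and 7.94.

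Suspended soleus also carried more fast-fibre transcripts than Ct, with Myh4 rather than Pvalb leading. Myh4, the fastest myosin of rodent limb muscle, was higher by 5.72 (52.8-fold), Myh1 by 3.94 and the fast troponin Tnni2 by 2.91, whereas Pvalb was higher by only 0.45. Of 16 fast-fibre genes, 12 were at least 1.5-fold higher and none lower, with a median of 1.19 against a random range of -0.10 to 0.18. Slow-fibre genes had a median of -0.29, below a range of -0.20 to 0.17, with 3 of 15 at least 1.5-fold lower and 1 higher; Myh7b stood at -1.69, Myl3 at -0.51, Myh7 at -0.38 and Ankrd2 at 0.09. Myh1 and Myh4 are closely related in sequence, so their probe sets may not be fully specific.

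Developmental genes were higher in TS with a median of 0.54 and 5 of 13 members at least 1.5-fold higher, including Ankrd1 (3.35), Myh3 (2.44), Myod1 (1.92) and Myog (1.42), while Tnnt2 stood at 0.45 and Chrng at 0.20. Denervation-responsive regulators had a median of 0.80 against a range of -0.04 to 0.24, with 7 of 12 at least 1.5-fold higher, such as Cdkn1a (2.21), Runx1 (1.99) and Gadd45a (1.35). Neuromuscular junction genes had a median of 0.07, within range, and their members went both ways. Musk was higher by 1.05 and Lrp4 by 0.67, while of the receptor subunits Chrnb1 was higher by 0.68 and Chrna1 and Chrnd were lower, at -1.31 and -1.16. The p53 target list had a median of 0.08, within range, although its mean (0.39) lay above, with Tp53inp1 at 0.93 and Phlda3 at 0.91 beside Cdkn1a and Gadd45a.

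Genes of mitochondrial energy metabolism were lower in TS as well. Fatty acid uptake and oxidation genes had a median of -0.80, with 19 of 27 at least 1.5-fold lower, including Fabp3 (-2.09) and Hadh (-1.21), and with Angptl4 higher (1.57). Oxidative phosphorylation subunits had a median of -0.55, with 20 of 45 at least 1.5-fold lower and none higher; Cox8b stood at -1.15, Atp5mc1 at -1.05 and Ndufs3 at -0.85. The median of tricarboxylic acid cycle genes was -0.42, with 5 of 18 lower, Mpc1 at -1.08, and the pyruvate dehydrogenase kinase Pdk4 higher by 1.36. Oxidative regulators and angiogenic genes had a median of -0.28, with Perm1 (-2.20) and Vegfa (-1.2) lowest. Glycolysis and glycogen genes had a median of 0.03, within range, with 5 of 24 at least 1.5-fold higher, Phkg1 (1.05) among them, and 1 lower, Ldhb (-0.95).

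Lists of cell cycle genes, proteasome subunits and ribosomal proteins stood above their random lists in TS. Cell cycle genes had a median of 0.58 against a range of 0.00 to 0.14, with 8 of 17 at least 1.5-fold higher, among them Ccnb1 (1.10), Rrm2 (1.09), Mcm6 (1.08) and Mcm5 (1.07). These 4 were dim in Ct, at 6.14, 6.78, 6.61 and 6.02, and the mean used for the filter includes their TS values. Proteasome subunits had a median of 0.35, with 2 of 31 members past 1.5-fold, Psmd11 (0.65) and Psmd8 (0.62). Ribosomal protein genes had a median of 0.26, with Rpl36 (0.77) and Rps19 (0.67) among 4 of 34 past 1.5-fold. Over all 10154 genes, 598 were at least 1.5-fold higher in TS than in Ct. Fbxo32 was higher by 0.65, a 1.57-fold difference, and Trim63 by 0.55, while the list of ligase and ubiquitin genes had a median of 0.09, within range, with Fbxo31 at 0.59 and Asb2 at -1.43. Centring takes 0.13 from every TS minus Ct difference and so brings Fbxo32, Fbxo31, Psmd11, Psmd8 and Rps19 under 1.5-fold. Excitation-contraction coupling genes had a median of 0.28 and growth factor and FOXO signalling genes of 0.30, both above their ranges. The latter list was led by the metallothioneins Mt2A (2.10) and Mt1 (1.82), which also sit on the antioxidant list, and by Fst (1.08) and Igfbp5 (0.83). Fkbp5 and Klf15, named below as targets of the glucocorticoid receptor, are members of the same signalling list. Antioxidant genes had a median of -0.09, below their range, although their mean was 0.10 and lay within it. Medians within their ranges were those of autophagy genes (0.03), heat shock genes (0.05), extracellular matrix genes (0.11), polyamine genes (0.05), interferon and antigen presentation genes (0.00) and complement and cytokine genes (0.10). Under centring of each array, which shifts a list and its random lists alike, the medians of the neuromuscular junction, p53 target, circadian, ubiquitin, glycolysis, autophagy, heat shock, matrix, polyamine and complement lists turned negative. The means of the heat shock list (-0.07) and of the median-negative satellite cell (0.11) and lymphocyte (0.02) lists had the opposite sign to their medians. With the trend removed or with quantile normalization, the interferon list lay below its range (-0.10 and -0.12). Lox (1.47), Timp1 (1.56), Hspb6 (-0.90), Srm (0.87), B2m (-0.74) and Cfd (1.42) were among their members.

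Cell type markers in TS showed macrophage markers at a median of 0.48, above a range of 0.00 to 0.24, with 4 of 13 at least 1.5-fold higher, led by Cd163 (1.17) and Mrc1 (0.95). Adipocyte markers had a median of 0.52, with Adipoq (1.62), Cfd (1.42) and Cidec (1.16) higher, and tendon markers a median of -0.75, with Kera (-1.37), Chad (-1.35) and Tnmd (-1.22) lower. Endothelial markers had a median of -0.03, below a range of -0.01 to 0.23, a call that ended under 3 alternatives, with Kdr at -0.73. Satellite cell (0.00), smooth muscle (0.00), fibroblast (0.00), lymphocyte (-0.01), neutrophil and mast cell (0.00) and Schwann cell and nerve markers (0.00) lay within their ranges. Single members that differed were Chodl (-0.90), Met (0.86), Pdgfra (0.81), Erbb3 (0.92) and Egr2 (-0.82).

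At the 2-fold limit, 139 genes were higher and 70 lower in TS than in Ct, 66.5% higher. Centring each array on its median turned this to 90 higher and 120 lower, 42.9% higher; removing a trend on expression gave 56.5% and quantile normalization 51.8%, so the balance of directions in TS depends on the scaling. With 32 added to each value on the linear scale, 91 genes were higher and 56 lower, 61.9% higher. Further genes at the upper end were Alb (2.78), which encodes serum albumin, B3galt2 (2.75), Mybph (2.66), the cytokine-inducible Cish (2.39) and Chi3l1 (2.31). At the lower end were Tecrl (-2.97), Asb18 (-2.95), Tceal7 (-2.50), Slc41a3 (-2.41), the glycerol channel Aqp7 (-2.31), Mettl21c (-2.26), Lgi1 (-2.08) and Bdh1 (-1.94), an enzyme of ketone body use. All 8 genes past 2-fold that had a further probe set past the filter limit differed in the same direction there, 5 of them again past 2-fold.

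**Figure D2:**
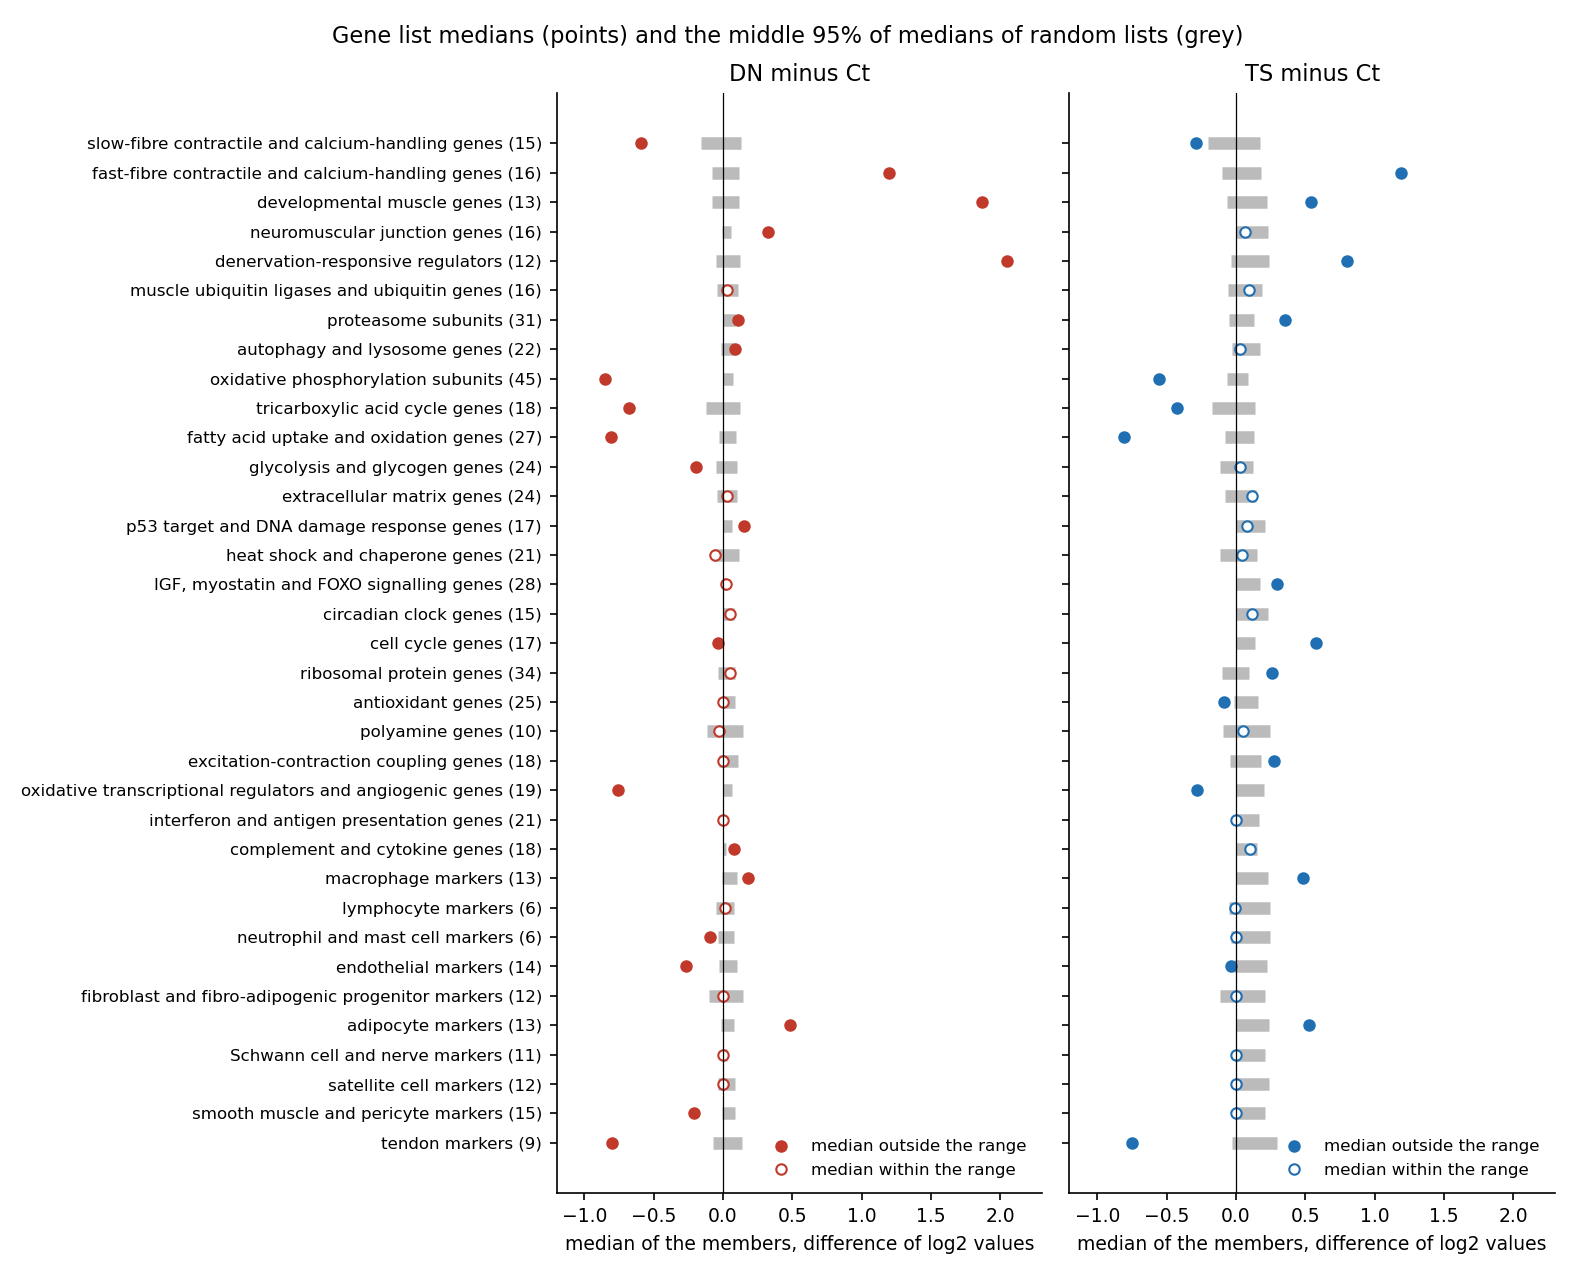
Medians of 35 gene lists as differences of log2 values (horizontal axis), DN minus Ct on the left and TS minus Ct on the right, with the number of measured members after each name. Grey bars span the middle 95% of medians of 10000 random lists, and filled points lie outside it, as for 10 lists above and 11 below in DN and 10 above and 8 below in TS.

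Set directly against TS, the DN pool had more transcript of the acetylcholine receptor subunits Chrna1 and Chrng and less of the fastest myosin, Myh4. Chrna1 was higher in DN than in TS by 4.89 (29.7-fold), Emb by 4.77, Chrng by 4.56, the peptidylarginine deiminase Padi2 by 4.04, Ctxn3 by 3.95 and Ppp1r14c by 3.92. Myh4 was lower in DN (-3.71), as were Scn4b (-3.49), Car14 (-3.47), Asb11 (-3.31), the water channel Aqp4 (-3.26) and Ifit1 (-3.11). Ifit1 (3.71), Car14 (5.03) and Aqp4 (5.64) in DN and Ppp1r14c in TS (5.46) read below the filter limit of 5.72. Denervation-responsive regulators had a median of 1.17, developmental genes of 0.56 and neuromuscular junction genes of 0.30, all above their random ranges. Antioxidant genes (0.10) also lay above. Below their ranges were fast-fibre genes (-0.38), cell cycle genes (-0.77), glycolysis and glycogen genes (-0.40), oxidative phosphorylation subunits (-0.33), tricarboxylic acid cycle genes (-0.38), oxidative regulators (-0.33), excitation-contraction coupling genes (-0.35), macrophage markers (-0.30), ribosomal protein genes (-0.20) and proteasome subunits (-0.14). The proteasome call ended under 4 alternatives, and those for antioxidant genes and macrophage markers ended when the mean was taken (0.08 and -0.30). Fatty acid genes (0.00) and slow-fibre genes (-0.18) lay within. In all, 122 genes were at least 2-fold higher and 177 lower in DN than in TS, 40.8% higher, against 56.2% with centred arrays, 49.1% with the trend removed and 50.7% with quantile normalization.

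The differences of DN and TS from Ct shared many genes. Of those at least 2-fold different, 57 were higher in both, among them Ankrd1, Myh1, Myh3, Myod1 and Cdkn1a, and 45 were lower in both, among them Mettl21c, Perm1, Lgi1, Asb18, Tecrl and Aqp7. Independent lists of these sizes would share 3.11 and 1.56 genes, and simulated unchanged arrays that share Ct gave 11.4 and 11.8. The simulated noise was scaled to the DN minus TS differences, which hold both treatments, but lacked their extremes. With the same noise, 1.44% of unchanged genes passed 2-fold, against 2.94% of genes in DN minus TS. The simulated numbers therefore do not bound what a shared Ct array can give. At the same limit 3 genes went in opposite directions, Chrna1 and Chrnd, higher in DN and lower in TS, and Aqp4, the reverse, against 0 in the simulation and 4.67 for independent lists. Across genes, which are not independent replicates, the correlation of the differences was 0.533 (Pearson) and 0.442 (Spearman), against 0.50 and 0.479 in the simulation. The covariance was 0.0845 against 0.0792, and part of the sharing may come from the common Ct array, which cannot be split.

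**Figure D3:**
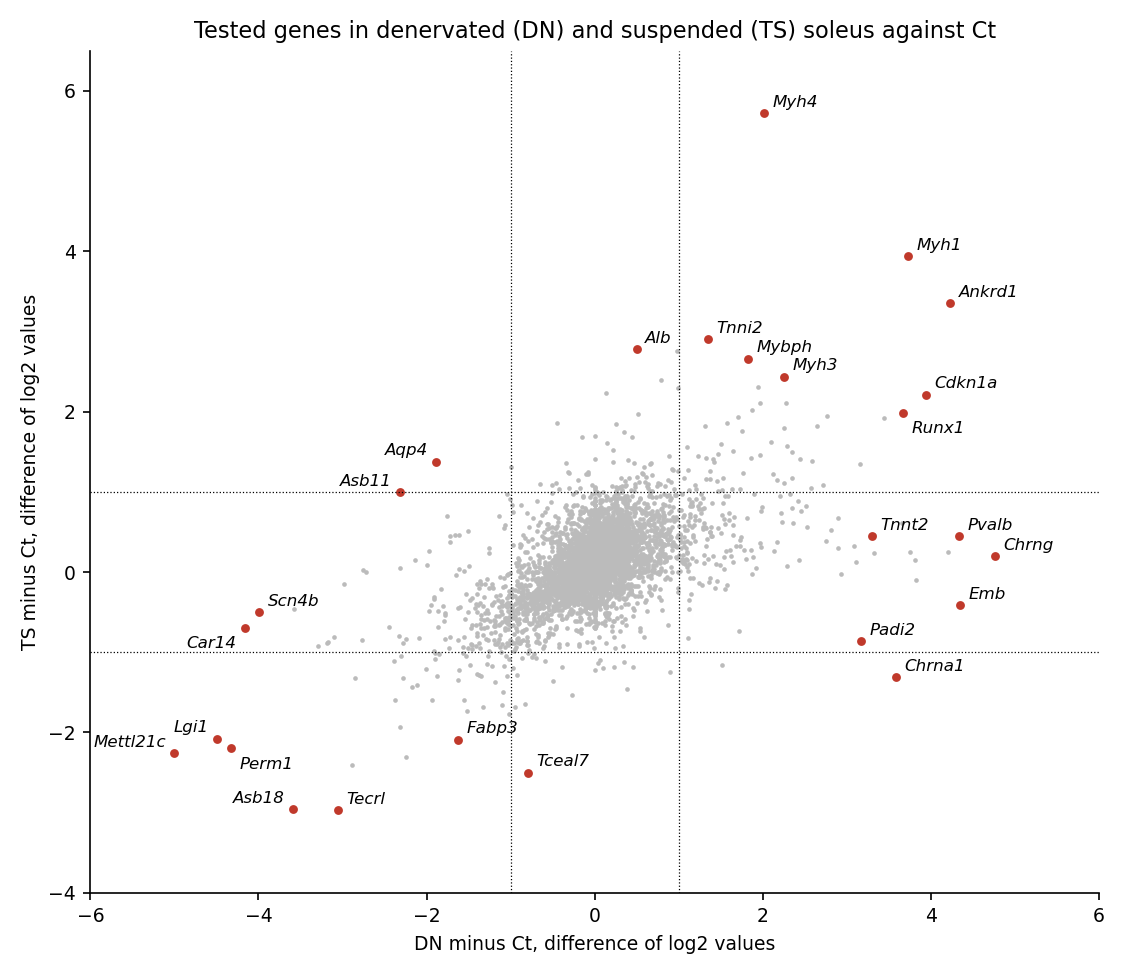
Each point is 1 of 10154 genes, with its DN minus Ct difference on the horizontal and its TS minus Ct difference on the vertical axis (log2); dotted lines mark the 2-fold limit and red points are selected genes. Myh4 lies at 2.02 and 5.72, Chrna1 at 3.58 and -1.31, and Mettl21c at -5.00 and -2.26.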

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

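The tests of a floor on dim probe sets, of fast muscle carried into either pool, of shared myosin signal, of liver RNA and of scaling were chosen after the result was seen; the test of median polish was set before. Several genes lay on opposite sides of Ct in DN and TS by at least 1.5-fold, and with 1 array per group these differences between DN and TS were not tested. Chrna1 was higher in DN than in TS by 4.89 (log2), Padi2 by 4.04 and Egr2 by 1.40. Asb11 stood at -3.31, Aqp4 at -3.26 and Ccnb1 at -1.75, lower in DN than in TS. The median of cell cycle genes was lower in DN than in TS (-0.77), which was likewise not tested; against Ct it was 0.58 in TS but only -0.04 in DN, where tied values narrowed the random range to 0.00 at both ends. A further 6562 probe sets with a mean at or above the filter limit of 5.72 had no gene name or several, and no comparison used them. Of these, 65 were at least 2-fold higher and 110 lower in DN than in Ct, and 63 higher and 136 lower in TS.

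More than 1 in 3 probe sets carried exactly the same value on a pair of arrays, and on Ct and DN 57.0% of all probe sets did. A floor confined to dim probe sets is argued against, since 20.3% of probe sets with a mean of 10 or more were also equal on Ct and DN. Ties were still less common among brighter probe sets, at 18.8% for a mean of 12 or more on Ct and DN. Median polish of 3 simulated unchanged arrays gave equal values in 83.9% of pairs with 25 probes and 31.0% with 10, while 4 arrays gave 0.0%. The simulation used 1 noise level and gave 83.3% to 84.2% for each pair at 25 probes. It therefore does not address the fall with brightness, nor the lower share of 37.7% on Ct and TS. The ties may therefore come from the summary step on so few arrays. No biological explanation was tested.

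Fast-fibre genes were far higher in TS and DN than in Ct, with Myh4 leading in TS (5.72) and Pvalb in DN (4.34). Fast muscle with its usual transcripts carried into the TS pool is argued against by Pvalb, which lay -2.46 from the median of the 5 other members below 9 in Ct. Signal shared between myosin heavy chain probe sets is argued against for the whole list by 9 of 13 other members at least 1.5-fold higher in TS (7 in DN). Myh1 signal in the Myh4 probe set is argued against for TS by their DN minus TS differences, 3.50 apart. For DN it stays open, since Myh1 read 11.99 and Myh4 only 8.48 there, so a small part of the Myh1 signal could raise Myh4. Myh4 signal in the Myh1 probe set in TS also stays open, the TS minus Ct difference of Myh1 lying -1.79 from that of Myh4. Fast muscle carried into the DN pool stays open. Myh4, which Myh1 signal may have raised, lay 0.66 above the median of the other dim members there. Lower values of Mylk2 and Myoz1, both bright in Ct, could come from the soleus itself. Myh1, Myh4, Myl11, Tnnc2, Tnni2, Tnnt3, Tpm1 and Actn3 were at least 1.5-fold higher than Ct in both DN and TS. Pvalb passed this limit only in DN, and Myh2, Atp2a1, Myoz1 and Mybpc2 only in TS. That loss of nerve and loss of load raise fast-fibre genes to different degrees may be considered as a hypothesis that the design names. This hypothesis is untested without replicates.

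Alb (2.78), Hpd (1.86) and Hpx (1.42), known as liver transcripts, were higher in TS than in Ct. All were dim in Ct, at 5.98, 6.60 and 5.25. Hpx also read 5.25 in DN and 6.67 in TS, so it passed the filter at 5.72 only through its TS value. With the trend on mean expression removed, the smallest of the 3 differences was 1.41. The TS median lay only 0.13 above that of Ct, so this test could hardly have come out otherwise. An array-wide shift is too small to give these differences, whereas effects on single probe sets were not tested. A trace of liver RNA stays open: the highest difference among Apoa1, Apoa2, Fgb and Serpina1 was 0.31, but all 4 were dim on every array, and Fgb and Serpina1 lay below the filter. The 7 measured liver genes besides Alb, Hpx and Hpd, Apoa1 and Apoa2 among them, had a median of 0.01, within their random range. An effect of suspension stays open as a hypothesis, untested without replicates.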

How the results depend on the processing

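Leaving out genes with equal values was chosen after seeing the data; the other alternatives were planned. Centring the arrays gave 90 genes at least 2-fold higher and 120 lower in TS than in Ct, because it takes the same 0.13 from every TS minus Ct difference although the median of these was 0.02, and 32 added on the linear scale gave 91 higher, because it damps dim genes. At a 1.5-fold limit, 501 genes were higher and 562 lower in DN than in Ct, 598 and 272 in TS than in Ct, and 325 and 602 in DN than in TS. At a 3-fold limit the counts were 95 and 71, 35 and 19, and 50 and 52. All other counts of genes, of shared genes and of lists outside their range stayed within 1.5 times the main count under the alternatives run. The correlation of the differences ran from 0.508 to 0.562 and the genes shared by both comparisons from 78 to 115. Of 3960 values of 169 named genes under 8 settings, 48 lay on the other side of the 2-fold limit and 0 called values changed sign; Musk, Fst and Phkg1 in TS were among the former under each scaling. Of 1032 list medians or means, 20 lost and 26 gained their place outside the random range, and the cause was not tested. The slow-fibre, fast-fibre, developmental, neuromuscular junction, denervation-responsive, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid and cell cycle lists kept their calls against Ct under every alternative run. No paired analysis was possible because each group has a single array. Signal over background limits dim genes, and no detection value was used here.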

Other observations

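The grouping of genes by symbol was chosen after the values were seen; the test of glucocorticoid-induced genes was set before its result. Genes of the mitochondrial ribosome were lower in DN, with a median of -0.22 (log2) over 41 large-subunit genes (Mrpl), of which 9 were at least 1.5-fold lower, and of -0.13 over 27 small-subunit genes (Mrps), of which 0 were. In TS the medians were -0.04 and -0.02, also below their random lists, with 1 Mrpl and 0 Mrps genes at least 1.5-fold lower. Coenzyme Q synthesis genes (Coq, 11 measured) had medians of -0.62 in DN and -0.33 in TS, with Coq8a at -1.96 and Coq10a at -1.42 in DN. Among 11 groups above their random lists in TS were histone genes (0.52, 4 of 8 at least 1.5-fold higher), cytosolic small-subunit ribosomal genes (Rps, 0.41, 8 of 33 higher and 2 lower), elongation factors (Eef, 0.31, 3 of 11), nucleoporins (0.27, 4 of 18, with Nup210 at 0.82) and initiation factors (Eif, 0.14, 2 of 44). Rps (0.07, against an upper bound of 0.05) and Eef (0.18) also lay above their random lists in DN, with 0 of 33 Rps genes at least 1.5-fold higher and 1 lower, and 1 of 11 Eef genes higher. Chemokine genes of the Ccl group had a median of 0.30 in DN, with 2 of 10 higher. None of these medians changed sign under centring, trend removal or quantile normalization, but centring, which shifts random lists alike, moved the TS medians of Eif to 0.008, Nup to 0.135, Eef to 0.17, Mrpl to -0.18 and Mrps to -0.15. Of 156 symbol groups with at least 8 members, 12.8% lay outside the middle 95% of 2000 random lists in DN and 14.1% in TS, against 5.0% for random lists. Symbol groups hold related genes, whose probe sets may share signal, and some, such as Rps, overlap the lists described above. The 5.0% is therefore not the share to be awaited for such groups, and the excess was not tested.

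Circadian clock genes had medians of 0.05 in DN and 0.12 in TS, within their ranges, the latter turning negative under centring, although 4 of 15 were at least 1.5-fold higher and 3 lower in DN. Bhlhe41 was higher by 1.73 and Dbp by 1.39, Nfil3 stood at -1.92, and Nr1d1 was higher by 0.82 in DN and 0.97 in TS. Erythroid markers had 3 measured members, with Hbb at -0.36 in DN and 0.56 in TS, Alas2 at -0.43 and 0.45, and Hbb-b1 at -0.53 and -0.11. Among 3 measured keratinocyte and hair markers, Tp63 was higher by 1.52 in DN and 1.03 in TS and the others were near 0. Of 8 Y-linked genes only 1 was named on the array, and it did not pass the filter, so the sex of the rats cannot be read from this list. In all, 26 genes lay at least 1.5-fold on opposite sides of Ct in DN and TS, 8 higher in DN and 18 lower in DN. Among the first were the immediate early gene Egr1 and the epoxide hydrolase Ephx1 (1.72 in DN), and among the second the gluconeogenic Fbp2 (-0.87 in DN, 0.84 in TS) and the potassium channel Kcna7 (-1.75 and 0.70).

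Fkbp5 (1.22), Klf15 (0.72), Pdk4 (1.36) and Zbtb16 (0.75), known targets of the glucocorticoid receptor, were higher in TS than in Ct, while in DN they stood at -0.08, -0.30, -0.34 and -0.97. A glucocorticoid response to suspension may be proposed as a hypothesis. The median of 18 other glucocorticoid-induced genes in TS was 0.18, at percentile 95.2 of its random lists and within their range of -0.01 to 0.20, with 3 members at least 1.5-fold higher. This leaves the hypothesis open, since the median lay high but not outside the range.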
